A study of Mus musculus with 6 samples.

How the data were processed

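RNA was measured in 6 Smart-seq2 libraries of neurons sorted from the hippocampal dentate gyrus of mice carrying a tamoxifen-inducible Cre under control of the activity gene Fos and a Cre-dependent tdTomato reporter (TRAP2;Ai9). Smart-seq2 copies polyadenylated RNA along its whole length and amplifies the cDNA by PCR, without molecular identifiers, so reads are not independent molecules. In the TRAP2;Ai9 mouse, cells that are active while tamoxifen is present stay red for good, and the cells of interest here had been labelled around a learned helplessness procedure. Fluorescence-activated cell sorting then isolated the red cells. Of the 6 libraries, 3 came from mice that afterwards had no running (NR) and 3 from mice that ran voluntarily for 28 days (Run). The labels place all 6 libraries in 1 batch. They describe sorted neurons as the material and single-cell sequencing as the method, and the number of cells and of animals behind each library is not given in the sources used here. The p-values therefore measure only the spread between these libraries, which may be technical.

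The deposited values are FPKM, a count of fragments scaled by transcript length and by the mapped fragments of the library, in 1 table of 55367 gene symbols with a column per library. Per the submitters' processing notes, the tools included Trimmomatic 0.39, STAR 2.7.5c and StringTie 2.1.7, and the genome build was mm10. The notes give neither the role of each tool nor the annotation, so which tool made the FPKM values is not given in the sources used here. No symbol occurred more than once. Of the symbols, 53289 (96.2%) matched the GENCODE M21 annotation of the same build, from which gene coordinates and transcript lengths were taken. Reads shared between near-identical genes may have been split between them, so values of ribosomal protein genes, tubulins, Akr1b10 and the mitochondrial-like pseudogenes of chromosome 1 are uncertain to that extent.

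FPKM values hold no read totals, so depth could be inferred only by assuming what 1 read is worth. For genes with a single annotated transcript, FPKM was multiplied by transcript length. Among steps tried within a fixed range, the step with the most values at it and at its double was taken as 1 read. It was 24.3, 27.8 and 27.9 FPKM times base pairs in NR replicates 1, 2 and 3 and 26.6, 23.3 and 26.8 in Run replicates 1, 2 and 3. Only 31, 45 and 48 values in NR and 51, 44 and 42 in Run lay within 1% of 1 or 2 steps, against medians of 12 to 15 over the steps tried, while 28.7% to 31.1% of 2868 to 3265 values per library lay under 3 steps, so most low values were no whole multiples. A step chosen for the highest count lies above the median in any case, so these counts do not show that a step exists. If the step is 1 read, the libraries lay within 1.20-fold of each other in depth. Such small counts and the fixed range of steps leave this uncertain. The FPKM summed over all symbols ranged from 473786 to 492021. No pair of libraries shared their values: at least 99.99% of the values above 0 in either library differed between any 2 of them.

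FPKM values were tested on the scale log2(FPKM + 1) without further scaling, for genes with FPKM of at least 1 in at least 3 of the 6 libraries, which left 6155 genes. Every difference is Run minus NR on the log2(FPKM + 1) scale, which understates changes of genes with low values. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A looser count of genes at an unadjusted p under 0.05 with a log2 difference of at least 1 in size was kept beside it. The 35 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, in lists with at least 4 tested members, with adjustment over the lists tested. Measures of whole libraries, 17 in all, were compared with a 2-sided exact permutation test of the difference in means, which cannot give a p below 0.1 with 3 libraries against 3. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

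An FPKM of 0 can be a failed estimate. Of 12 genes that every cell uses, 5 were listed at 0 in at least 1 library, among them Tbp, the TATA-binding protein, at 0 in all 3 Run libraries. A gene is therefore said to be listed at 0, never absent, and genes below FPKM 1 in some library are given as values per library. Means ± SD are given for genes with FPKM of at least 1 in all 6 libraries.

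The groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where a later choice is stated. By that rule the text names up to 15 genes per direction past the adjusted threshold or, where fewer than 10 pass, fills up to 10 with the smallest unadjusted p among non-overlapping genes with a log2 difference of at least 1 in size. It also names the 3 tested members of each list with the smallest p, the 2 members of each cell type list with the highest mean, and 13 genes fixed in advance; 3 genes that the rule selects are not reported here. Predicted genes and pseudogenes were left out of the names and kept in the totals. Genes named outside this rule, chosen after their values were seen, are those of highest mean FPKM, the ribosomal RNA and mitochondrial-like pseudogenes, Snap25, Camk2a, C1qc, Tbp, and those in the first paragraphs of the closing section.

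The gene test was tried on simulated data of 6155 genes for Run against NR in 5 runs, in which log2 changes of 1, 2 and 4 were added to 335, 335 and 330 genes over all runs. With a noise SD of 0.760 on the log2 scale, taken from abundant genes, limma recovered 3.28% of the changes of 1, 41.8% of the changes of 2 and 100% of the changes of 4, with 3.8 false calls per run. This noise gave every gene the same SD, whereas real genes differ in spread, so these shares do not give the power of the real test. With the real values of each gene shuffled over the libraries as noise, it recovered 0.299%, 1.19% and 4.85%, with 0 false calls. The alternatives covered the pseudocount, the filter, the scaling, the trend, library weights, the replicate number as a block, the list test and each library left out in turn.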

Results

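The design set mice that ran against mice that did not, and asked how running changes dentate gyrus neurons that had been active around a stress experience. Learned helplessness, a state in which animals stop escaping after exposure to stress they cannot control, is a rodent model used in depression research. Full-length RNA profiles of tdTomato-positive neurons were available for 6 libraries, 3 without running (NR) and 3 with running (Run). The number of genes with FPKM of at least 1 was 5426, 7355 and 5980 in NR replicates 1, 2 and 3 and 6291, 6136 and 5534 in Run replicates 1, 2 and 3. The means were 6254 ± 993 and 5987 ± 400 (SD, n = 3 each; exact permutation p = 0.9, where 0.1 is the smallest that 3 libraries against 3 allow). Only 1751 genes reached FPKM 1 in all 6 libraries, and 83.1% of all values in the table were 0. Across genes, which are not independent replicates, the log2 profiles of libraries of the same group correlated with a mean Pearson r of 0.417 over 6 pairs, and those of different groups with 0.425 over 9 pairs.

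The most abundant messenger RNAs of the sorted material included several of genes known from glia. Cst3, the secreted protease inhibitor cystatin C, had the highest mean of the nuclear protein-coding genes at 5532 ± 1581 FPKM (SD over 6 libraries), followed by Apoe, the brain's main lipid carrier, at 4379 ± 2468. The ferritin heavy chain gene Fth1 (2984 ± 701), the metallothioneins Mt1 (2892 ± 938) and Mt3 (1810 ± 629), the glycolytic enzyme gene Aldoc (1864 ± 666) and the chaperone gene Clu (1803 ± 1001) were also among the highest. Ribosomal RNA at CT010467.1 (chromosome 17, 39846353 to 39848827) took 6.02% to 8.65% of the summed FPKM of a library. Mitochondrially encoded genes took 13.2% ± 1.46 in NR and 12.5% ± 2.98 in Run (exact permutation p = 0.6). The 10 highest genes of a library held 20.8% ± 1.30 of its sum in NR and 19.6% ± 3.16 in Run (exact permutation p = 0.7).

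Markers of dentate granule neurons, the principal cells of this region, were detected sparsely. None of the 15 granule neuron markers reached FPKM 1 in all 6 libraries, and 9 stayed below 1 in every library. Prox1 (chromosome 1, 190118035 to 190170714), the transcription factor that specifies granule cell identity, had 0.285, 17.8 and 0.417 FPKM in the NR libraries and 3.65, 39.9 and 15.1 in the Run libraries. Calb1, which encodes the calcium buffer calbindin, was listed at 0, 15.4 and 0 in NR and had 23.2, 44.3 and 6.41 in Run. The synaptic organiser gene C1ql2 had 0, 68.3 and 28.4 in NR and 31.4, 3.06 and 0 in Run, and Stxbp6 had 0, 30.7 and 0.296 in NR and 102, 15.1 and 0 in Run. Rbfox3, which encodes the neuronal nuclear protein NeuN, had 0, 49.7 and 0 in NR and 119.5, 5.62 and 18.2 in Run. Snap25, of the synaptic release machinery, was more even, at 172, 249 and 454 FPKM in NR and 370.2, 390.5 and 169 in Run. It was chosen after its values were seen, and only 6 of 26 synaptic vesicle genes reached FPKM 1 in all 6 libraries. Camk2a, the kinase of excitatory synapses, had 66.1, 55.2 and 48.9 in NR and 106, 37.3 and 47.2 in Run.

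Immature granule neuron markers were better covered, with 5 of 13 at FPKM of at least 1 in all 6 libraries. Stmn1, a regulator of microtubules in growing neurites, had 338 ± 173 FPKM in NR and 607 ± 140 in Run (SD, n = 3 each), a log2 difference of 0.97 ± 0.51 (SE). The neuronal tubulin gene Tubb3 had 94.6 ± 81.1 and 183 ± 99.1. Dcx, which encodes doublecortin of newborn neurons, had 0, 0.805 and 3.50 in NR and 24.7, 0 and 19.8 in Run, and Sox4 had 0, 12.6 and 0.186 in NR and 29.7, 5.87 and 6.13 in Run. By limma's camera test, neither the granule list (4 tested, 3 positive, median log2 difference 1.97) nor the immature granule list (9 tested, 6 positive, median 0.97) passed, each with an adjusted p = 0.499. As library measures, the mean log2(FPKM + 1) of the granule list was 0.77 ± 0.73 in NR and 1.16 ± 0.60 in Run, and that of the immature list 3.06 ± 1.03 and 3.56 ± 0.41 (exact permutation p = 0.7 for each).

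Markers of other hippocampal neurons were also detected sparsely. The mean log2 levels of the CA pyramidal and interneuron lists were near those of the granule list, 0.77 in NR and 1.16 in Run. Of the CA pyramidal list, 6 of 11 markers were below FPKM 1 in every library and none was above it in all 6. Bok had 0.0247, 36.5 and 113.8 FPKM in NR and 1.59, 0 and 0 in Run, and Dkk3 had 3.57, 59.0 and 21.1 in NR and 30.5, 0 and 29.6 in Run. Slc17a7, the vesicular glutamate transporter of excitatory neurons, was listed at 0, 0.750 and 0 in NR and 29.5, 7.75 and 0 in Run. The interneuron gene Gad1, which encodes a GABA-synthesising enzyme, had 43.4, 1.38 and 31.9 in NR and 46.4, 19.2 and 0 in Run, and the neuropeptide gene Cck had 52.4, 0 and 47.4 in NR and 0, 0 and 65.0 in Run. Vip was above FPKM 1 only in Run replicate 3, at 155.9, and Dlx1 had 0, 50.7 and 42.5 in NR and 17.6, 0 and 17.0 in Run. Among mossy cell markers, Calcrl was above FPKM 1 only in Run replicate 3 (47.3), and Ociad2 in NR replicate 2 (1.71) and Run replicate 1 (24.9). The CA pyramidal, interneuron and mossy cell lists had 2, 3 and 0 tested members, too few for the list test. Their mean log2 levels were 0.92 and 0.80 (exact permutation p = 0.9), 0.91 and 1.05 (p = 0.8), and 0.27 and 0.49 (p = 1) in NR and Run.

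Astrocyte transcripts were present in every library at high levels in both groups. Of the 12 astrocyte markers, 10 reached FPKM 1 in all 6 libraries. Aldoc had 1816 ± 815 FPKM in NR and 1913 ± 662 in Run, and Gfap, the intermediate filament of astrocytes, had 866 ± 271 and 818 ± 414 (SD, n = 3 each). Sox9, a glial transcription factor, had 88.7 ± 62.1 in NR and 31.2 ± 5.27 in Run. S100b had 0, 73.8 and 62.6 in NR and 87.1, 14.7 and 174 in Run, and Fgfr3 had 37.8, 20.6 and 20.4 in NR and 0.327, 21.5 and 31.5 in Run. The mean log2 level of the list was 6.95 ± 0.30 in NR and 6.71 ± 0.64 in Run (exact permutation p = 0.9), the highest of the 13 cell type lists in both groups. Of the 12 tested markers, 8 had a negative log2 difference, with a median of -0.36, and the list did not pass camera (adjusted p = 0.852).

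**Figure D1:**
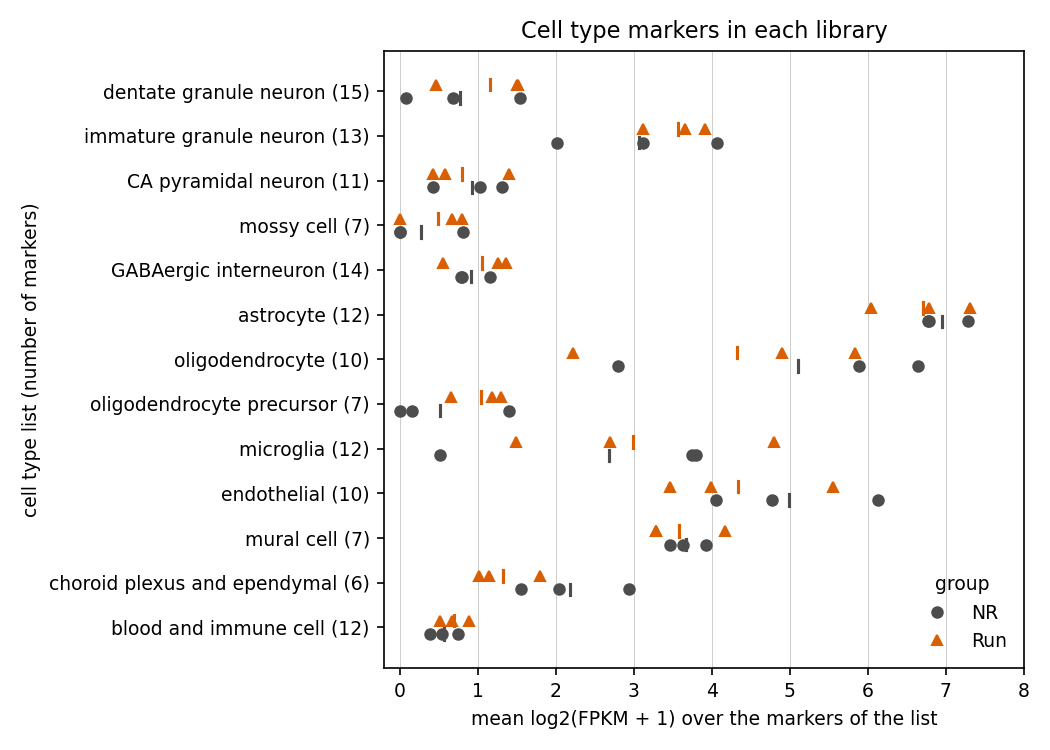
Mean log2(FPKM + 1) of each cell type list (horizontal axis) in the 3 NR libraries (circles) and the 3 Run libraries (triangles), with a short vertical line at each group's mean and the number of markers in brackets. Astrocyte markers have the highest group means, 6.95 in NR and 6.71 in Run, while granule neuron markers average 0.77 and 1.16.

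Myelin and vascular genes were also present and varied widely between libraries of the same group. The myelin gene Mbp had 282 ± 187 FPKM in NR and 115 ± 124 in Run (SD, n = 3 each). Opalin had 48.9, 17.1 and 29.9 in NR and 0.0192, 40.2 and 0.0173 in Run, and Mobp had 23.6, 100.1 and 139.8 in NR and 0.109, 41.7 and 87.5 in Run. Of 10 oligodendrocyte markers 8 had a negative log2 difference (7 after quantile normalization), with a median of -0.41 and a camera adjusted p = 0.541. Without NR replicate 1, whose oligodendrocyte level was the lowest of its group, the list passed at the preset correlation (adjusted p = 0.0387, lower values in Run) and not at an estimated correlation of 0.428 (adjusted p = 0.988). Run replicate 1, which had the lowest mean log2 level of all 6 libraries (2.21, against 2.79 in NR replicate 1), stayed in that fit. The endothelial genes Ly6c1 and Cldn5, the latter a tight junction component, had 759 ± 431 and 369 ± 276 in NR and 766 ± 232 and 223 ± 67.4 in Run. Flt1, a receptor for vascular growth factors, had 50.0 ± 12.1 and 21.2 ± 10.01. Pecam1 had 0.00948, 25.2 and 0.0743 in NR and 13.4, 47.3 and 44.4 in Run, and Cdh5 had 5.93, 9.97 and 4.09 in NR and 10.3, 0 and 0 in Run. The endothelial list did not pass (7 of 10 negative, median -1.23, adjusted p = 0.541).

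Microglial, mural, precursor, choroid plexus and blood markers completed the survey of other cells. C1qb, a complement component made by microglia, had 0, 37.9 and 5.41 FPKM in NR and 64.0, 220.2 and 130 in Run (log2 difference 4.29 ± 1.45 SE, limma adjusted p = 0.715). Its partner C1qa had 0.293, 96.1 and 128 in NR and 49.5, 282 and 108 in Run, and the signalling adaptor gene Tyrobp had 0, 214 and 268 in NR and 0, 194 and 0.0718 in Run. The microglia list did not pass (7 tested, 4 positive, median 0.55, adjusted p = 0.873), and C1qc was its only member at FPKM 1 in all 6 libraries. The contractile genes Acta2 and Tagln of mural cells had 533 ± 418 and 207 ± 123 in NR and 319 ± 156 and 115.5 ± 96.0 in Run, while Rgs5 had 69.4 ± 28.9 and 108 ± 38.8. Olig1, of the oligodendrocyte lineage, had 0, 0.0625 and 18.5 in NR and 13.8, 17.7 and 38.8 in Run, and the precursor marker Lhfpl3 exceeded FPKM 1 only in NR replicate 3 (37.9). Ttr, the thyroid hormone carrier of the choroid plexus, had 0, 96.3 and 39.97 in NR and 0.0772, 23.1 and 35.8 in Run. The ciliary genes Ccdc153 (31.5, 51.8 and 117.7 in NR, 62.6, 0 and 0 in Run) and Tmem212 (18.8, 3.65 and 0 in NR, 0, 0 and 45.9 in Run) were no steadier. Lyz2, a lysozyme of myeloid cells, had 101 ± 83.2 in NR and 208 ± 121 in Run, whereas the leukocyte gene Ptprc exceeded FPKM 1 only in NR replicate 2 (1.69) and Run replicate 2 (4.22). Of 12 blood and immune markers 10 were below FPKM 1 in every library. The mural, precursor, choroid plexus and blood lists had 3, 1, 3 and 1 tested members and no list test.

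As library measures, none of these lists separated the groups. Mean log2 levels in NR and Run were 5.11 ± 2.04 and 4.32 ± 1.88 for oligodendrocytes and 4.98 ± 1.06 and 4.33 ± 1.09 for endothelium (exact permutation p = 0.5 for each). Microglia had 2.69 ± 1.88 and 2.99 ± 1.67 (exact permutation p = 1), mural cells 3.67 ± 0.24 and 3.58 ± 0.51 (p = 0.8), and precursors 0.52 ± 0.76 and 1.04 ± 0.34 (p = 0.4). Choroid plexus and ependymal markers had 2.18 ± 0.70 and 1.32 ± 0.42 (exact permutation p = 0.2), and blood 0.56 ± 0.18 and 0.69 ± 0.19 (p = 0.5). Adjusted over the 17 library measures, every one of these exact p-values became 1.

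The comparison of runners with non-runners asked which genes differ in the labelled neurons after 28 days of running. No gene passed. The genes with the smallest p had values in 1 group and were at or near 0 in the other. Among those with values in Run, Tln2 (chromosome 9, 67217087 to 67559703), which encodes the integrin-binding protein talin 2, had 3.01, 3.40 and 3.21 FPKM, against 0, 0.00539 and 0 in NR, a log2 difference of 2.07 ± 0.34 (SE). Tmem208 (chromosome 8, 105326354 to 105335219), an endoplasmic reticulum protein gene, had 66.0, 75.9 and 71.9 in Run, and Stip1 (chromosome 19, 7020702 to 7039967), a co-chaperone of heat shock proteins, 85.0, 47.7 and 62.2. Both were listed at 0 in all 3 NR libraries. Rrm2, a subunit of the enzyme that makes DNA precursors, had 107, 42.1 and 190.0 in Run and at most 0.0188 in NR. Akr1b10 (chromosome 6, 34384218 to 34396950), an aldo-keto reductase gene with close paralogs, had 111, 92.3 and 79.0 in Run and at most 0.0200 in NR. Blcap had 78.7, 81.7 and 113 in Run and at most 0.0309 in NR, and the vesicle transport gene Bet1 had 35.1, 108 and 79.5 in Run and at most 0.0603 in NR. Fam20b, a kinase gene of proteoglycan synthesis, had 8.61, 14.1 and 6.18 in Run. Coq5, of coenzyme Q synthesis, had 16.0, 13.4 and 14.1, and the potassium-chloride cotransporter gene Slc12a7 had 18.4, 16.3 and 14.7, all 3 genes being listed at 0 in NR.

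In the opposite direction, Rnf14 (chromosome 18, 38284537 to 38317849), which encodes a RING-type ubiquitin ligase, had 145, 167 and 75.1 FPKM in NR and 0.165, 0.0337 and 0.730 in Run, a log2 difference of -6.59 ± 1.08 (SE). The chromatin regulator gene Baz1b (chromosome 5, 135187264 to 135246129) had 4.87, 4.05 and 4.93 in NR and 0, 0.00492 and 0 in Run. Rbpms (chromosome 8, 33782643 to 33929863), encoding an RNA-binding protein, had 10.4, 11.4 and 9.62 in NR and at most 0.00213 in Run. Sdf2, an endoplasmic reticulum protein gene, had 58.0, 96.2 and 97.3 in NR and at most 0.167 in Run. Values in NR were 233, 50.7 and 102 for Mea1, 55.6, 50.1 and 122 for the mitochondrial import gene Tomm34, and 51.3, 70.0 and 62.9 for Apopt1, which acts in cytochrome c oxidase assembly. Slc35b2, a Golgi transporter of the sulfate donor, had 90.1, 48.9 and 45.8 in NR, Kpna4, a nuclear import receptor, 6.41, 3.22 and 2.56, and Filip1l 5.005, 3.52 and 2.101. Filip1l was listed at 0 in all 3 Run libraries, where Mea1, Tomm34, Apopt1, Slc35b2 and Kpna4 had at most 0.0441.

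**Figure D2:**
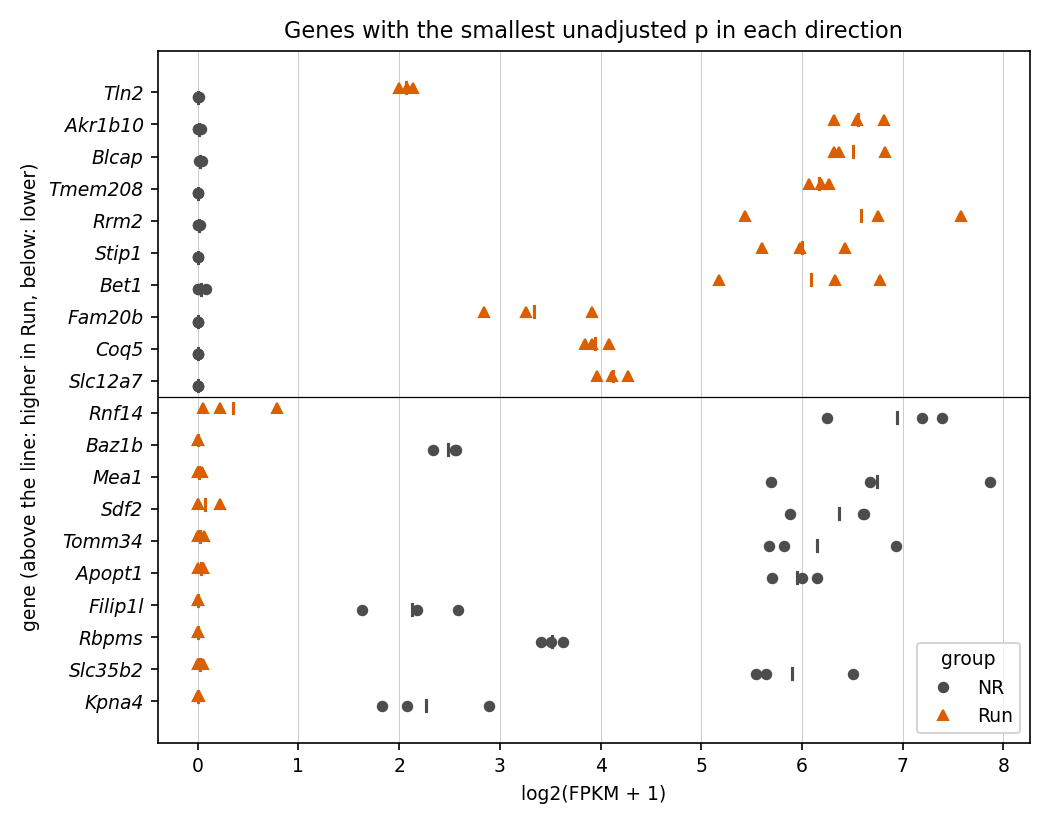
Values on the log2(FPKM + 1) scale (horizontal axis) of the 10 genes with the smallest unadjusted p in each direction, in the 3 NR libraries (circles) and the 3 Run libraries (triangles), with a vertical line at each group's mean. Every gene sits at or near 0 in all libraries of 1 group, and none passed the adjusted threshold (adjusted p = 0.244 for each).

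By limma, 0 of the 6155 tested genes reached an adjusted p under 0.05, and these 20 genes each had an adjusted p = 0.244. At an unadjusted p under 0.05 there were 304 genes, against 307.75 for a test with no differences at all. With a log2 difference of at least 1 in size, 149 of them had higher values in Run and 152 lower. The values of the groups did not overlap for 551 genes (8.95%, where chance gives 10%), 293 with Run above and 258 with Run below. A total of 63 genes had FPKM of at least 1 in all 3 Run libraries and below 1 in all 3 NR libraries, and 81 showed the opposite. Without NR replicate 2 the count of higher genes was 226 in place of 149. The precision behind these counts differed between classes of abundance: the median residual SD on the log2 scale was 1.41 for 1827 genes with a mean below 10 FPKM, 2.45 for 3635 genes with a mean of 10 to 100 FPKM, 0.797 for 648 genes with higher means and 0.387 for the 45 genes with the highest. In simulated data of this size, log2 changes of 2 were recovered in 1.19% of cases at the spread of the real values. They were recovered in 41.8% when every gene was given the same SD, taken from abundant genes, unlike the real genes. The absence of calls therefore does not show that running left expression unaffected.

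**Figure D3:**
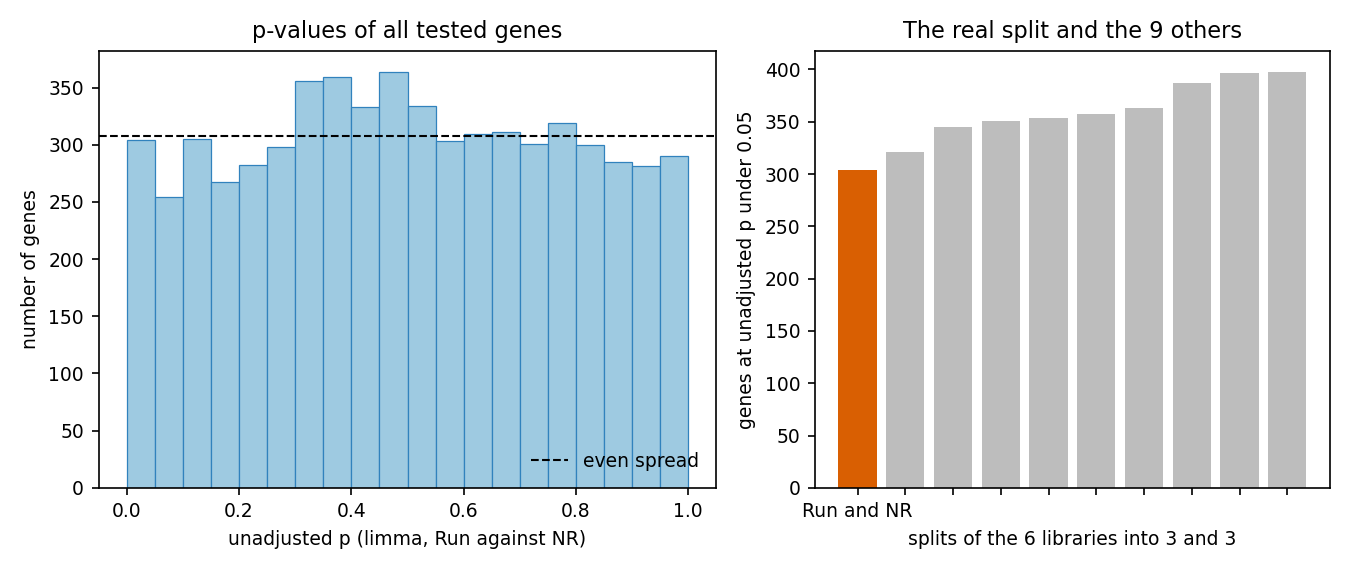
Left, the number of tested genes (vertical axis) in each bin of unadjusted limma p for Run against NR (horizontal axis), with the even spread of a test without differences as a dashed line; the bin under 0.05 holds 304 genes. Right, the number of genes at an unadjusted p under 0.05 for the grouping into Run and NR (304) and for the other 9 ways of dividing the 6 libraries into 3 and 3 (grey, 321 to 398).

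Immediate early genes, which neurons switch on within minutes of activity, were expressed in both groups. Transcripts of other cells were also present in the libraries, and which cells gave these values was not tested. Fos, the gene whose promoter drove the labelling, had 378, 67.6 and 590 FPKM in NR and 525, 130 and 394 in Run. Nr4a1, an activity-induced nuclear receptor, had 271 ± 113 in NR and 109 ± 45.8 in Run (SD, n = 3 each; log2 difference -1.28 ± 0.58 SE). Fosb had 49.4, 13.0 and 88.9 in NR and 44.8, 0 and 16.3 in Run, and Nr4a2 had 1.89, 44.8 and 27.5 in NR and 50.5, 0 and 0 in Run. Arc, a regulator of synaptic receptor trafficking, had 32.3, 0 and 9.60 in NR and at most 0.0297 in Run, while Npas4 exceeded FPKM 1 only in Run replicate 1 (9.48). None of the 12 tested members passed, 6 had positive and 6 negative differences, and the list had a median of -0.02 and a camera adjusted p = 0.921. Of the later activity-regulated genes, the opioid peptide gene Penk had 63.2, 19.5 and 46.8 in NR and 0, 41.9 and 0.0250 in Run. Plk2 had 20.1, 40.4 and 18.4 in NR and 0.0347, 37.2 and 0.0774 in Run, and Nptx1, a pentraxin of excitatory synapses, 0, 17.8 and 20.6 in NR and 29.9, 24.5 and 53.0 in Run. Bdnf, the neurotrophin most often tied to exercise, had 0, 0.413 and 17.6 in NR and 15.9, 0.973 and 0 in Run. The later list had 4 positive and 4 negative members (median 0.02, mean -0.34, adjusted p = 0.989), and its median became -0.14 when libraries were rescaled to an equal sum and 0.28 after quantile normalization.

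Receptor genes for GABA, the main inhibitory transmitter, had lower values in Run for 5 of 6 tested members. Gabra4 had 7.29, 11.7 and 15.6 FPKM in NR and 13.0, 5.06 and 0 in Run. The list had a median log2 difference of -1.51 and did not pass camera (adjusted p = 0.419). Glutamate receptor genes were detected less often, with 13 of 24 below FPKM 1 in every library, against 3 of 14 GABA receptor genes. Gria2 had 0, 25.8 and 0 in NR and 8.77, 3.39 and 5.77 in Run, Gria1 had 0, 1.09 and 10.5 in NR and 11.96, 13.0 and 0 in Run, and Grin2b had 0, 7.24 and 0.656 in NR and 3.43, 2.32 and 0.00427 in Run. With 3 tested members the glutamate list had no list test. Receptors for monoamines and acetylcholine were below FPKM 1 in every library for 19 of 22 genes, and none was tested.

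Genes of synaptic vesicles had positive differences in 8 of 11 tested members. Syn1 and Syp, proteins of the vesicle surface, had 0, 31.6 and 8.36 FPKM and 0.0189, 47.9 and 81.3 in NR, and 67.9, 25.7 and 9.82 and 100.3, 48.0 and 55.1 in Run. Syn2 had 12.7, 10.7 and 23.2 in NR and 0.381, 16.3 and 0 in Run. Among postsynaptic scaffold genes, Dlgap3 had 0, 4.86 and 0 in NR and 18.5, 0 and 15.7 in Run, Dlgap1 had 9.34, 54.7 and 13.3 in NR and 1.31, 39.0 and 0.630 in Run, and the adhesion gene Nlgn3 had 0, 0.00639 and 23.8 in NR and 23.9, 13.0 and 1.62 in Run. Of the potassium channel genes, Kcnk1 had 44.7 ± 26.0 in NR and 49.4 ± 10.3 in Run (SD, n = 3 each). Kcnip3 had 34.5, 0 and 73.1 in NR and 0.0276, 26.2 and 0 in Run, and Kcnab2 had 0.0104, 1.45 and 21.7 in NR and 0, 15.3 and 0 in Run. The vesicle list (median 0.29, adjusted p = 0.873), the scaffold list (6 of 10 positive, 5 under median-ratio or quantile scaling, median 0.33, adjusted p = 0.921) and the channel list (2 of 4 positive, median -0.13, adjusted p = 0.921) did not pass camera.

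Stress hormone genes had positive differences in 8 of 10 tested members. Tsc22d3, a target of the glucocorticoid receptor, had 107 ± 58.6 FPKM in NR and 219 ± 91.1 in Run, and the kinase gene Sgk1, another such target, had 58.8 ± 57.3 and 138 ± 84.9 (SD, n = 3 each). The log2 differences were 1.16 ± 0.68 and 1.71 ± 1.23 (SE). Nr3c1, the glucocorticoid receptor itself, had 23.3, 5.52 and 0.00662 in NR and 13.3, 16.7 and 16.6 in Run, and its co-chaperone gene Fkbp5 had 0, 4.79 and 0 in NR and 0.212, 9.13 and 0 in Run. The list had a median of 0.74 and did not pass camera (adjusted p = 0.499). Of the exercise-linked trophic genes, Ntrk2, the receptor for brain-derived neurotrophic factor, had 54.2 ± 18.8 in NR and 86.1 ± 39.4 in Run. The growth factor receptor genes Fgfr1 and Igf1r had 43.5, 20.3 and 17.8 and 2.13, 0.737 and 5.32 in NR, and 0.292, 23.0 and 3.21 and 0.00258, 2.18 and 0 in Run. That list did not pass either (2 of 6 positive, median -0.86, adjusted p = 0.741).

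Protein quality control genes were mixed. Hsp90b1, an endoplasmic reticulum chaperone, had 3.64, 92.4 and 0 FPKM in NR and 61.0, 191 and 36.5 in Run. Asns, which makes asparagine, had 27.2, 0 and 52.1 in NR and 58.7, 10.5 and 131.6 in Run, and the disulfide isomerase gene Pdia6 had 0.0184, 23.7 and 0.109 in NR and 40.7, 110.6 and 0.0166 in Run. The unfolded protein response list had 8 positive members of 12 (median 1.41, camera adjusted p = 0.499). Among heat shock genes, the mitochondrial chaperonins Hspe1 and Hspd1 had 152 ± 25.7 and 52.0 ± 16.9 in NR and 88.3 ± 89.0 and 98.1 ± 43.1 in Run. Dnajb1 had 47.7, 46.3 and 158.9 in NR and 58.0, 39.3 and 0.0725 in Run. The heat shock list had 5 of 9 positive, a median of 0.05, a mean of -0.24 and an adjusted p = 0.921.

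Cytosolic ribosomal protein genes were detected in every library, all 77 of them, and 51 had positive differences (49 under quantile normalization). Rps2 had 228 ± 59.4 FPKM in NR and 495 ± 129 in Run, Rps24 had 344 ± 20.8 and 623 ± 136, and Rps3 had 155 ± 29.0 and 309 ± 35.3 (SD, n = 3 each). Their log2 differences were 1.11 ± 0.39, 0.83 ± 0.31 and 1.00 ± 0.40 (SE). The list had a median of 0.25 and did not pass camera (adjusted p = 0.419; adjusted p = 0.992 with an estimated correlation, as for every other list tested). At the preset correlation it passed without Run replicate 2 (adjusted p = 0.0178) and with no filter on low values (adjusted p = 0.0177), and with an estimated correlation it passed in neither case (adjusted p = 0.502 and 0.943). The share of summed FPKM in these genes was 4.80% ± 0.259 in NR and 5.42% ± 1.29 in Run (exact permutation p = 0.4), with 6.20%, 3.93% and 6.13% in Run replicates 1, 2 and 3.

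Energy metabolism genes showed no common direction. Of 74 tested nuclear genes of oxidative phosphorylation, 36 had positive and 38 negative differences (34 and 40 under the other scalings). Atp5g1, a subunit of the ATP synthase ring, had 49.5 ± 72.0 FPKM in NR and 185 ± 70.6 in Run (SD, n = 3 each). The complex I gene Ndufs1 had 24.7, 5.31 and 0.0679 in NR and 36.1, 96.6 and 71.3 in Run, whereas Ndufa9 had 75.9, 38.7 and 33.9 in NR and 48.3, 0 and 0 in Run. The mitochondrially encoded complex I genes mt-Nd4, mt-Nd5 and mt-Nd1 had 2482 ± 656, 899 ± 410.5 and 5242 ± 922 in NR and 1713 ± 517, 1340 ± 481 and 6030 ± 826 in Run. The glycolytic genes Aldoa and Ldha had 1320 ± 375 and 192 ± 67.7 in NR and 957 ± 228 and 115 ± 90.3 in Run, and Gpi1 had 73.5, 94.1 and 0.0364 in NR and 34.3, 174 and 162 in Run. Camera adjusted p-values were 0.921 for oxidative phosphorylation (median -0.03, mean 0.07), 0.989 for mitochondrially encoded genes (9 of 13 positive, 7 under median-ratio or quantile scaling, median 0.05, mean -0.02) and 0.989 for glycolysis (6 of 16 positive, median -0.14, mean 0.10). Cholesterol synthesis genes had 4 of 9 positive, a median of -0.17 and an adjusted p = 0.921. Msmo1 of that pathway had 91.6 ± 52.8 in NR and 139 ± 34.8 in Run. Insig1, a brake on sterol synthesis, had 62.1, 14.3 and 31.3 in NR and 16.8, 0 and 24.8 in Run, and Cyp51 had 0, 33.3 and 27.8 in NR and 0, 7.74 and 0 in Run.

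Immune, matrix and cell death genes likewise gave no list past the threshold. B2m, the invariant chain of MHC class I, had 1208 ± 504.5 FPKM in NR and 794 ± 389 in Run (SD, n = 3 each). The antiviral gene Bst2 had 61.1, 36.3 and 49.4 in NR and 0.0803, 43.0 and 18.7 in Run, and Isg15 had 0, 18.0 and 0.0587 in NR and 31.6, 28.7 and 0 in Run. The interferon and MHC list had 2 of 8 positive (median -0.17, camera adjusted p = 0.921). Ptprz1, a receptor phosphatase that binds the matrix, had 8.23 ± 10.3 in NR and 43.6 ± 24.4 in Run, while the metalloprotease inhibitor gene Timp3 had 120 ± 104 and 51.5 ± 35.3. Timp2 had 2.77, 51.5 and 0 in NR and 0, 1.75 and 0 in Run. The matrix list had 2 of 8 positive (median -0.63, adjusted p = 0.921). Cdkn1a, a cell cycle inhibitor induced by DNA damage, had 118 ± 29.7 and 82.5 ± 47.9. The survival gene Bcl2l1 had 57.7, 19.2 and 86.9 in NR and 125, 25.7 and 0 in Run, and the death gene Bax had 0, 54.0 and 57.8 in NR and 43.2, 31.3 and 45.7 in Run. The apoptosis list had 5 of 7 positive (4 after rescaling to an equal sum), a median of 0.14 and an adjusted p = 0.989.

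Across the 24 lists tested, 0 passed camera at an adjusted p under 0.05, with the preset or with an estimated correlation. The remaining 11 lists had fewer than 4 tested members. Among these, the nuclear RNA Malat1 had 492 ± 102 FPKM in NR and 323 ± 117 in Run (SD, n = 3 each), and Peg13 had 9.11, 10.1 and 0 in NR and 2.82, 0 and 0 in Run. Xist, the RNA that silences an X chromosome in females, was listed at 0 in every library. The Y-linked genes Eif2s3y and Ddx3y had 25.5, 17.0 and 0 and 0.0115, 15.02 and 18.9 in NR, and 0, 1.16 and 18.2 and 0.0198, 6.21 and 14.5 in Run. Over all 35 lists no member passed when adjusted over all genes, and 1 member passed when adjusted over the list alone.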

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

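The fits to genes with a mean FPKM of at least 100 and to libraries rescaled without ribosomal RNA, mitochondrial genes and their chromosome 1 copy, and the list tests with an estimated correlation under other alternatives, were chosen after the data were seen; the other alternatives were planned. No gene passed an adjusted p under 0.05 by limma in any of the 18 alternatives, and the lowest adjusted p ranged from 0.0567 without a mean-variance trend to 0.968 for genes with a mean of at least 100. The count of genes higher in Run at an unadjusted p under 0.05 with a log2 difference of at least 1 in size, 149 as reported, was 131 to 226 when 1 library was left out (226 without NR replicate 2) and 6 among genes with a mean of at least 100. The count lower in Run by the same rule, 152 as reported, was 136 to 221 when 1 library was left out, 97 among genes with a mean of at least 10 and 8 among those with a mean of at least 100. Fewer genes were tested under both of these filters; the cause of the count without NR replicate 2 was not tested. Gene lists past the threshold, 0 as reported, numbered 1 with no filter (ribosomal proteins, adjusted p = 0.0177) and 0 to 1 when 1 library was left out: 1 without NR replicate 1 (oligodendrocyte markers, adjusted p = 0.0387) and 1 without Run replicate 2 (ribosomal proteins, adjusted p = 0.0178). These 3 passes were at the preset correlation; with an estimated one none of the 3 passed (adjusted p = 0.943, 0.988 and 0.502), and the cause was not tested further. Scaling moved the median log2 difference of all genes by at most 0.047. Of 118 tested named genes, none passed under any alternative and 18 changed sign under some, 16 of them only when a library was left out and 0 under a scaling. None of the 20 genes with the smallest p changed sign. This says little, since they were chosen for values that did not overlap between the groups. None of the 17 library measures moved by more than 1 SD. Leaving out 1 of 3 libraries cannot move a measure that far, so those fits decide nothing here. Only the changed detection threshold and the shares without mitochondrial genes could have done so, and the cell type measures had neither. With the replicate number as a block, 0 genes and 0 lists passed, with 116 genes higher and 132 lower by that looser rule. Same-numbered libraries deviated together only weakly across genes (r = 0.0211, 0.00416 and 0.0179 for numbers 1, 2 and 3). Each library nevertheless correlated best with its own number. Most tested genes were below FPKM 1 in some library, so these r values cannot decide whether the numbers pair the libraries. Some library measures followed the number: the mitochondrial share was highest in replicate 2 of both groups (14.9% in NR, 16.0% in Run). The mean log2 oligodendrocyte level was lowest in replicate 1 of both (2.79 and 2.21). The ribosomal protein share did not follow it, being lowest in NR replicate 1 and Run replicate 2. The libraries were not treated as pairs. What depth limits can be stated in reads only by assuming what 1 read is worth; at a mean of 10 to 100 FPKM, 78.9% of tested genes were below FPKM 1 in some library.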

Other observations

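The tests in this part, the splits of the libraries included, were chosen only after the results they bear on had been seen, and the genes in the next 2 paragraphs were chosen after their values were seen.

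Among 693 tested genes with a mean of at least 100 FPKM, where the spread between libraries was smaller, several had higher values in Run without passing the adjusted test. Chchd2 (chromosome 5, 129881156 to 129887470), a mitochondrial protein gene, had 391 ± 70.1 FPKM in NR and 835 ± 112 in Run (SD, n = 3 each), a log2 difference of 1.10 ± 0.29 (SE). The tubulin genes Tuba1a and Tubb5, which have close paralogs, had 837 ± 261 and 202 ± 54.1 in NR and 1604 ± 410.0 and 433 ± 121 in Run. Rhoa, a regulator of actin, had 50.9 ± 18.0 and 174 ± 82.3, Nrep, a gene linked to regenerating neurons, 45.8 ± 41.7 and 223 ± 45.1, and Acsbg1, which activates fatty acids, 65.6 ± 4.49 and 199.7 ± 86.6.

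Other abundant genes had lower values in Run. Fxyd5 (chromosome 7, 31032722 to 31042481), a modulator of the sodium pump, had 310 ± 84.6 FPKM in NR and 69.7 ± 25.5 in Run (SD, n = 3 each), a log2 difference of -2.18 ± 0.54 (SE). Anxa5, a phospholipid-binding annexin, had 259 ± 109 and 53.0 ± 29.1, and Sat1, which breaks down polyamines, had 495 ± 55.9 and 213 ± 67.3. Chchd10, a paralog of Chchd2, had 325 ± 106 and 131 ± 38.1, so that the lower values were in Run. The autophagy gene Map1lc3a had 343 ± 91.4 and 132 ± 84.3, and Bsg, a chaperone of lactate transporters, 1590 ± 443 and 967 ± 136. No gene passed the adjusted test. In the limma test of all 6155 genes, 22 of these abundant genes reached an unadjusted p under 0.05, 11 in each direction, against 34.65 for a test with no differences. A separate limma fit to 695 genes of this abundance alone had a lowest adjusted p of 0.968, and 17 reached an unadjusted p under 0.05.

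The library composition held a few further values. Pseudogenes of a mitochondrial segment on chromosome 1 (Gm10222, Gm28437, Gm10925, Gm28661 and Gm29216, 24612407 to 24616197) took 3.57% to 5.49% of the summed FPKM of a library.

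The counts for Run against NR were also taken under other groupings of the same libraries. There are 10 ways to divide 6 libraries into 3 and 3, too few for a share under 0.05, and where the real count is 0 every grouping gives as many, so that the comparison decides nothing about the lack of genes and lists past the threshold. The real grouping gave 0 genes past the adjusted threshold (highest of the others 0), 301 genes at an unadjusted p under 0.05 with a log2 difference of at least 1 in size (lowest of the others 316, highest 385) and 0 lists (highest of the others 3). The tests of running gave no call, which at this spread leaves an effect of running open.

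A total of 144 genes were at FPKM of at least 1 in all libraries of 1 group and below 1 in all libraries of the other, such as Tmem208, Stip1, Rnf14 and Baz1b. Whether too few sequenced reads explain them cannot be told from the values, since the step was searched only within a fixed range. Any step in that range would have given a high median. Assuming that 1 step of the low values is 1 read, a value above 1 in these genes was worth a median of 396 reads (lower quartile 153), over the 140 genes with an annotated transcript. The median was 132 if 1 read were worth 3 steps, and 66.4% of the low values were listed at 0. Loss of a gene's few starting molecules before or during amplification is a candidate explanation, since, by the mean FPKM over the libraries where a gene reached 1, the share of tested genes below 1 in some library was 81.6% at 10 to 100, 22.8% for 750 genes with higher means and 0% for the 45 genes with the highest, although it was no higher (69.8%) at means below 10. Such genes numbered 167 to 216 under the other groupings of the libraries, more than under the real one in each. None of these genes passed the adjusted test of running (lowest adjusted p = 0.244), and a real switch of some of them stays open.

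Astrocyte transcripts were abundant in libraries of cells sorted as neurons. Neuronal material alone, with weak detection of every kind of gene, is argued against, since 91.7% to 100% of astrocyte markers but 34.6% to 61.5% of synaptic vesicle genes reached FPKM 1 in a library, with a smallest gap of 30.1 percentage points. The lists were not matched for expression level, which limits this comparison. Transcripts of astrocytes in the sorted material may account for the astrocyte levels. In all 6 libraries 10 of the 12 markers were at FPKM of at least 1, with Aldoc at 1864 ± 666 FPKM and Gfap at 842 ± 314 (SD over 6 libraries). These values are the pattern itself and no separate test of that explanation. The tdTomato sort would be expected to remove unlabelled cells, and whether red astrocytes, cells attached to neurons or free RNA brought these transcripts was not tested. No biological explanation was tested for this pattern, since it is present in both groups.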
